A study of Bos taurus with 12 samples.

How the data were processed

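Right ventricle RNA of 12 Angus steers was extracted with Trizol and made into libraries by standard Illumina protocols, per the labels' protocols. The series used here has 1 table for all libraries. Per the file headers, the authors deposited RPKM (reads normalized to exon length and to the mapped reads of the library) for each of 24616 genes and 12 libraries, with Ensembl gene identifiers, symbols for 19987 of them and chromosome positions. The aligner, the counting, the use of strand and the genome build are not given in the sources used here, and positions are printed as the table gives them. The table also holds the authors' mean RPKM at low and high PAP, the fold change between these means and a p-value with its false discovery rate, per the file headers; which test gave the p-value is not given in the sources used here. In the deposited table the fold equals the ratio of the means, within 0.1%, in all 16388 genes for which both are finite numbers. The means fit an average over 7 libraries per pressure group, where 6 per group were used here. They are printed only as the authors' values.

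The groups, the comparisons, the tests, the lists of genes, the rule for named genes and most of the other settings were chosen before the data were examined. The tests chosen assumed counts, with limma-trend for a file without counts. Since the unit is RPKM, limma-trend was used. The number of reads behind each value was recovered from the RPKM values, since for each gene they are whole multiples of what 1 read is worth in that library. All 11374 tested genes came out as whole reads in every library within a tolerance of 0.05 reads. The recovered depth was 14739237 to 31090198 mapped reads per library, of which 85.6 to 88.2% fell in exons of the table's genes. Tested genes had a median of 370 reads per library, and 5% had fewer than 36. A gene with 1 kb of exon and 3 reads has 0.0965 to 0.204 RPKM. These depths limit counting error only. On simulated tables with known depth, the recovered reads were exact in 97.9% of 2938 genes, and in all 2007 genes with 30 or more reads.

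Genes with at least 1 RPKM in at least 3 libraries were kept (11374 of 17284 above 0), of which 10814 have a symbol. A symbol shared by several genes is followed by the identifier in all but the most abundant of them. MYH6 was on the lists but is not a symbol in the table, so no value is given for it. How reads that match several members of a gene family (myosin heavy chains, tubulins, actins, ribosomal proteins, MHC class II) were counted is not given in the sources used here, so values of single members are uncertain. limma 3.58.1 in R 4.3.3 (with statmod 1.5.0) was fitted to log2(RPKM + 1), with robust moderation and a trend of the variance with the mean, in 1 model of 3 groups without covariates. There were 4 comparisons, PH-failure with low PAP, PH-healthy with low PAP, PH-failure with PH-healthy, and the mean of both PH groups with low PAP. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted. Tables were read and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

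On simulated data with the groups and spread of these libraries, 2-fold changes were called in 81.8% of genes for PH-failure with low PAP (11196 genes run), 67.7% for PH-healthy with low PAP (11195), 64% for PH-failure with PH-healthy (11215) and 89.8% for all PH with low PAP (11209). For 4-fold changes these were 94.9%, 100%, 98.0% and 100%, with 12, 11, 10 and 9 unchanged genes called. Each gene was drawn independently, with 1 spread for all 3 groups. The PH-failure libraries were less alike (Spearman's correlation 0.932 to 0.960) than the PH-healthy ones (0.974 to 0.981). The shares called may thus be too high for the comparisons with PH-failure.

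Lists of genes for heart muscle, metabolism, signalling, stress, immune responses and other cell types, 45 in all, were tested against the other genes with limma's camera at a preset correlation of 0.01, with adjusted p over the 44 lists that had at least 3 measured genes. Beside it, camera was run with an estimated correlation and fry, a test of whether a list's genes move, on balance, in 1 direction. Each list also has its number of members past the threshold over all genes and adjusted over the list alone. Named genes follow a rule, per comparison. They are NPPA, NPPB, MYH6, MYH7 and ACTA1; the 8 called genes that rose most and the 8 that fell most, among genes with a symbol, a mean log2 value of at least 1 and no overlap between the groups; up to 4 genes of smallest p from each list called by camera; the 6 shared by both PH groups with the smallest larger p; and, where too few genes passed, the 4 of smallest p in each direction. Not all of the genes so chosen are reported here. Library measures (the mitochondrial share, the share of the 20 most abundant genes, depth, the exon share and the adipocyte score) were compared by 2-sided exact permutation tests over all 84, 20 or 924 groupings.

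The library names fall in series 55 (lane 4) and series 56 (lane 5), with 3 low-PAP libraries in each. PH-healthy replicate 1 and PH-failure replicates 1 and 2 are in series 56 and the others in series 55, and calls were also compared within each series. Spearman's correlation between libraries was 0.888 to 0.984, with no library repeated. Other settings chosen in advance were quantile normalization, pseudocounts of 0.1 and 0.5, no filter and a filter of 5 RPKM, only the groups compared, the library series as a term, a replicate block and leaving out each library. Median-ratio scaling, scaling to reads outside the mitochondrial genes, limma-voom on the recovered reads, the first component of the residuals as a term and the adipocyte score (log2 of the summed RPKM of ADIPOQ, CIDEC, PLIN4 and FABP4 plus 1) as a term were added after the data were seen.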

Results

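RNA was sequenced from the right ventricle, the chamber that pumps blood into the lungs, of 12 Angus steers that lived at an elevation of 2170 m (7120 ft) and were slaughtered at 13 to 15 months of age. Long exposure to the low oxygen of high altitude narrows the lung arteries of cattle and can raise the pulmonary arterial pressure (PAP), against which the right ventricle works. From repeated catheter measurements of PAP and from clinical signs, the animals had been classed as low PAP (6 animals), pulmonary hypertension without signs of failure (PH-healthy, 3 animals) or pulmonary hypertension with right heart failure (PH-failure, 3 animals). Each library is a different animal. The libraries held 14739237 mapped reads (PH-failure replicate 1) to 31090198 (low-PAP replicate 5), as recovered from the steps between low values. After removal of low values, 11374 genes were tested, with a median of 370 reads per gene and library. Group values are mean ± SD in RPKM (reads normalized to the length of the gene and to the mapped reads of the library), with n = 6, n = 3 and n = 3. Log2 fold changes are on the log2(RPKM + 1) scale, ± SE, which understates the change of genes with low values.

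The first principal component of the 12 libraries held 56.1% of the variance and separated both PH groups, at 10.6 to 41.9, from the low-PAP group, at -41.7 to -5.17. Low-PAP replicates 2 and 6 lay nearest to the PH libraries, at -11.9 and -5.17. PH-failure replicate 3 stood apart from the others on the second component, at 37.2. The 13 protein genes of the mitochondrial genome took 24.6 ± 2.67% of exon reads in the low-PAP group, 19.8 ± 1.27% in the PH-healthy group and 19.4 ± 1.34% in the PH-failure group. Each PH group differed from the low-PAP group by a 2-sided exact permutation test (p = 0.0119 in both, Benjamini-Hochberg adjusted p = 0.0397 over 20 tests of library measures), the smallest p that 6 against 3 allows. Within library series 56 the PH-failure and low-PAP means were 20.1% and 25.2%, and within series 55 they were 17.8% and 24.1%. For PH-healthy the means within series 56 and 55 were 20.3% and 19.5%. The median log2 fold change of all tested genes was 0.21 for PH-failure and 0.18 for PH-healthy against low PAP. Quantile normalization brought these medians to -0.03 and -0.04.

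**Figure D1:**
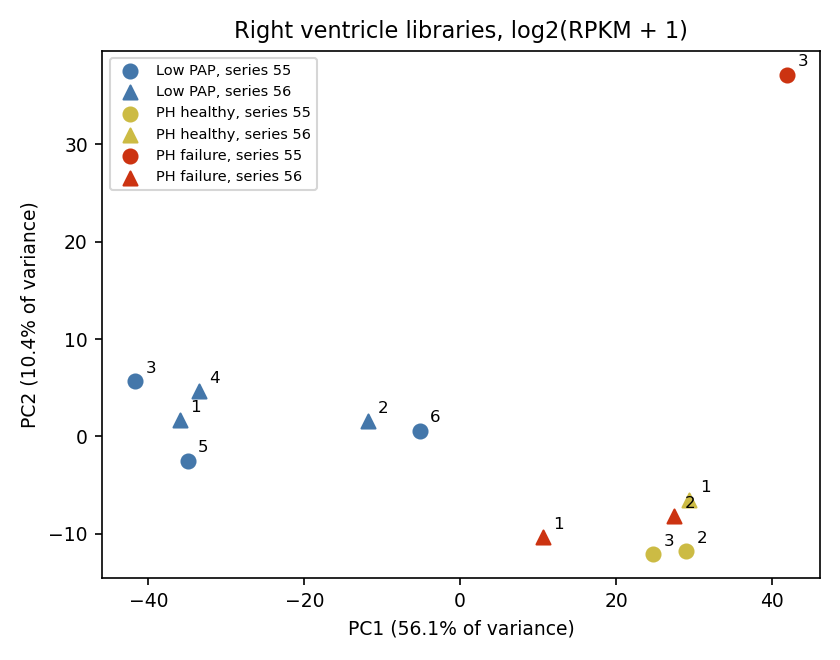
First and second principal components (percent of variance on the axes) of log2(RPKM + 1) in the 12 libraries, with color for the group, shape for the library series and the replicate number beside each point. The PH libraries lie at 10.6 or above on the first component and the low-PAP libraries at -5.17 or below.

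The comparison of PH-failure with low PAP asks how the ventricle of animals in right heart failure differed from that of animals that kept a low pressure at the same elevation. NPPB, which encodes B-type natriuretic peptide, a hormone released by stretched ventricular muscle, averaged 865 ± 732 against 19.9 ± 25.8 RPKM in PH-failure and low PAP, a log2 fold change of 5.82 ± 0.79 (limma adjusted p = 0.00114). NPPB was at 460, 426 and 1710 RPKM in PH-failure replicates 1, 2 and 3. It lies on chromosome 16 (ENSBTAG00000021739, 42700409 to 42701796). ANKRD2, a stretch-responsive muscle protein, rose to 285 ± 141 against 21.5 ± 8.52 RPKM (3.60 ± 0.34, adjusted p = 0.000136), and XIRP2, an actin-binding protein of muscle, rose to 100.2 ± 45.9 against 13.7 ± 4.36 RPKM (adjusted p = 0.000218). SCN3B, a sodium channel subunit, rose by 3.27 ± 0.59, RANBP3L by 3.34 ± 0.37, PPIP5K2 by 2.64 ± 0.30 and FSTL3, a secreted inhibitor of activins, by 2.60 ± 0.35 on the log2 scale. ACTA1, the skeletal muscle actin, averaged 2853 ± 2667 against 368 ± 397 RPKM (adjusted p = 0.0186), and its call was lost without PH-failure replicate 2 (adjusted p = 0.0774; 0.00653 to 0.0774 over its alternatives).

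Among genes that fell in PH-failure, MYL7, the atrial myosin light chain, averaged 899.9 ± 596 against 4812 ± 1525 RPKM, log2 fold change -2.57 ± 0.36 (adjusted p = 0.00115). MAOB, a mitochondrial amine oxidase, averaged 2.82 ± 3.07 against 21 ± 9.49 RPKM (adjusted p = 0.00186), HRASLS 6.54 ± 2.13 against 34.2 ± 7.74 RPKM (adjusted p = 0.000112) and PPP1R1A, an inhibitor of protein phosphatase 1, 19.5 ± 11.1 against 67.9 ± 16.8 RPKM (adjusted p = 0.0019). CA13, a carbonic anhydrase, TUBA1D and TRAT1 fell by 1.88, 2.34 and 1.83 on the log2 scale. The values of the PH-failure and low-PAP libraries did not overlap in these genes, as the rule for naming them required. Natriuretic peptide A (NPPA) averaged 96.3 ± 130.3 against 33.6 ± 33.9 RPKM and did not pass (adjusted p = 0.416), with 246 RPKM in PH-failure replicate 1. Its log2 fold change without that library was -0.32. Beta-myosin heavy chain (MYH7) averaged 3226 ± 726 against 2610.5 ± 436 RPKM (adjusted p = 0.202).

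**Figure D2:**
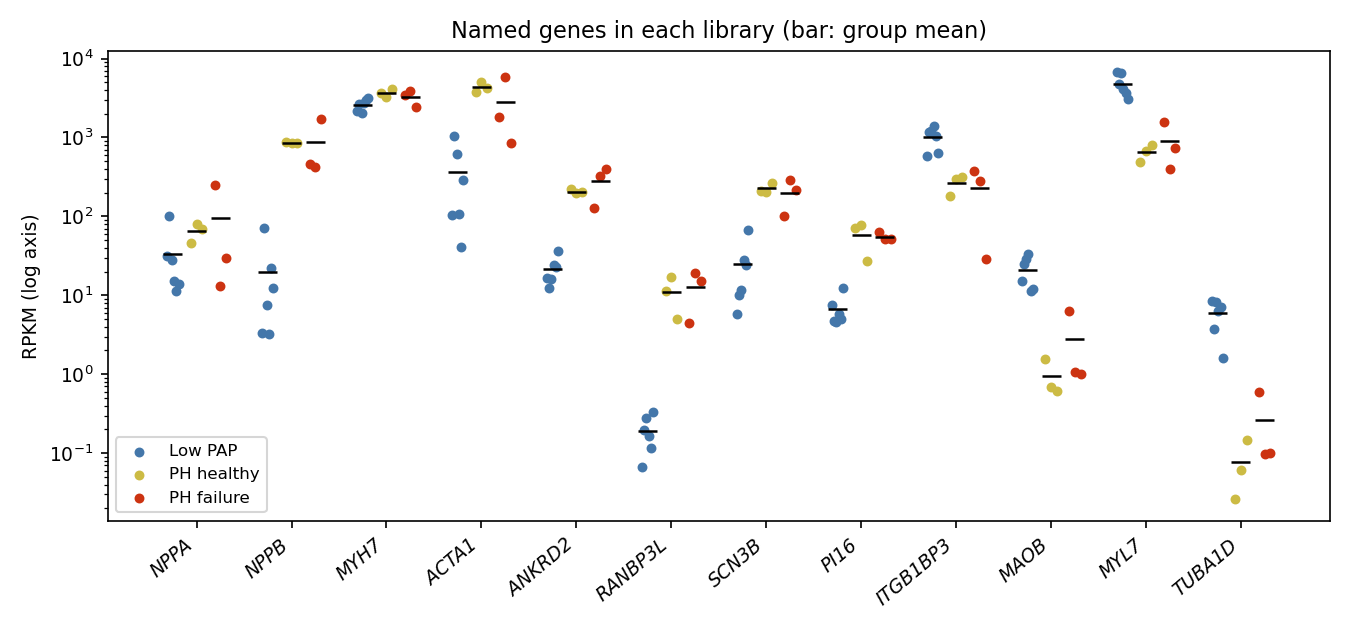
RPKM (log axis) of NPPA, NPPB, MYH7, ACTA1 and 8 of the genes that rose or fell most in PH-failure, 1 point per library, with color for the group and a bar at the group mean. NPPB averages 865 RPKM in PH-failure, 855 in PH-healthy and 19.9 in low PAP, while MYL7 averages 899.9, 652 and 4812. The PH-failure values of NPPB are 460, 426 and 1710 RPKM in replicates 1, 2 and 3.

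Of the extracellular matrix and fibrosis genes, 49 of 58 rose in PH-failure and none fell (50 adjusted over the list alone, 41 higher after quantile normalization; camera adjusted p = 1.16e-11, adjusted p = 0.833 with an estimated correlation). VCAN (versican), TIMP1 (an inhibitor of matrix proteases) and BGN (biglycan) averaged 5.30 ± 1.78 against 0.568 ± 0.219 RPKM, 71.7 ± 22.7 against 14.1 ± 2.81 RPKM and 146 ± 29.0 against 31.09 ± 9.02 RPKM. Of the fibroblast markers, 11 of 20 rose (14 adjusted over the list alone, 6 higher after quantile normalization; camera adjusted p = 0.0178, adjusted p = 0.851 with an estimated correlation). PI16 averaged 55.5 ± 6.77 against 6.64 ± 3.00 RPKM and COL1A1 116 ± 36.0 against 27.8 ± 7.97 RPKM. Of the growth and insulin/IGF signalling genes, 15 of 24 rose (16 adjusted over the list alone, 7 higher and 1 lower after quantile normalization; camera adjusted p = 0.00263, adjusted p = 0.833 with an estimated correlation). The growth factors PDGFD (1.71 ± 0.17) and FGF18 (1.55 ± 0.21) were among them. Of the BMP and TGF-beta signalling genes, 10 of 24 rose (13 adjusted over the list alone, 7 higher after quantile normalization; camera adjusted p = 0.0252, adjusted p = 0.851 with an estimated correlation). The receptors TGFBR2 (0.78 ± 0.14) and ENG (1.40 ± 0.27) rose. Of the macrophage and monocyte markers, 11 of 20 rose (13 adjusted over the list alone, 4 higher after quantile normalization; camera adjusted p = 0.0274, adjusted p = 0.851 with an estimated correlation), with the growth factor receptor CSF1R at 9.49 ± 2.06 against 3.77 ± 0.886 RPKM. Of the inflammatory cytokine and NF-kB genes, 11 of 18 rose (13 adjusted over the list alone, 4 higher after quantile normalization; camera adjusted p = 0.00971, adjusted p = 0.851 with an estimated correlation). The receptor IL1R1 was among them (1.27 ± 0.22). Of the complement and coagulation genes, 17 of 27 rose (21 adjusted over the list alone, 6 higher after quantile normalization; camera adjusted p = 0.00644, adjusted p = 0.851 with an estimated correlation). PROS1 (protein S, an anticoagulant) averaged 43.3 ± 15.5 against 9.74 ± 1.88 RPKM. The camera call was lost for BMP and TGF-beta signalling without PH-failure replicate 3 (adjusted p = 0.117; 0.00754 to 0.117 over its alternatives). That of the fibroblast markers was lost without low-PAP replicate 2 or PH-failure replicate 1 (adjusted p = 0.0625 and 0.153; 0.000196 to 0.153 over its alternatives). That of the macrophage and monocyte markers was lost without low-PAP replicate 2 or 6 or PH-failure replicate 1 (adjusted p = 0.0649, 0.0647 and 0.121; 0.000225 to 0.216 over its alternatives). That of the inflammatory cytokine and NF-kB genes was lost with the adipocyte score as a term (adjusted p = 0.0746; 0.000345 to 0.0746 over its alternatives). The adipocyte marker score of the libraries, on a log2 scale, was 7.67 ± 2.30 in PH-failure and 5.91 ± 1.1 in low PAP (exact permutation p = 0.155, adjusted p = 0.221 over the 20 tests).

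Of the 79 nuclear genes of oxidative phosphorylation, 52 fell in PH-failure and none rose (63 adjusted over the list alone, 34 lower after quantile normalization; camera adjusted p = 2.18e-34, adjusted p = 0.833 with an estimated correlation). COX7A1, a cytochrome oxidase subunit of muscle, averaged 1246 ± 345 against 2404 ± 465 RPKM, and NDUFB3, of complex I, averaged 306 ± 68.9 against 567 ± 113 RPKM. Of the TCA cycle genes, 6 of 22 fell (6 adjusted over the list alone, 6 lower after quantile normalization; camera adjusted p = 1.98e-05, adjusted p = 0.851 with an estimated correlation). SUCLA2 averaged 116 ± 22.9 against 179 ± 19.8 RPKM. Of the 40 fatty acid oxidation genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone, 10 and 3 after quantile normalization; camera adjusted p = 0.000245, adjusted p = 0.851 with an estimated correlation). HADHB, of the trifunctional protein of beta-oxidation, fell by 0.93, and the nuclear receptor PPARD rose by 0.98 on the log2 scale. Of the 13 genes of the mitochondrial genome, 3 fell (2 adjusted over the list alone, 1 lower after quantile normalization; camera adjusted p = 0.000589, adjusted p = 0.833 with an estimated correlation). Their median log2 fold change was -0.18, and 0.08 after quantile normalization. That normalization gives every library the same set of values, so the most abundant genes, such as COX1, can hardly differ and it decides little for them. Of the 74 cytosolic ribosomal protein genes, 2 fell (0 adjusted over the list alone, 1 lower after quantile normalization; camera adjusted p = 1.16e-11, adjusted p = 0.851 with an estimated correlation), with a median of -0.22 that became 0.01 after quantile normalization. Of the 14 T and NK cell markers, 4 fell (3 adjusted over the list alone, 6 lower after quantile normalization; camera adjusted p = 1.98e-05, adjusted p = 0.833 with an estimated correlation), at low values. TRAC averaged 3.76 ± 0.361 against 5.53 ± 0.512 RPKM, and its call was lost without PH-failure replicate 3 and with the adipocyte score as a term (adjusted p = 0.094 and 0.0908; 0.00524 to 0.142 over its alternatives). Of the 19 cell cycle genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 1 and 6 after quantile normalization). The list was lower relative to the other genes, with a median of -0.05 against 0.21 for all tested genes (camera adjusted p = 0.0274, adjusted p = 0.851 with an estimated correlation). This call was lost without low-PAP replicate 1 or 2 or PH-failure replicate 3, with the adipocyte score as a term and after median-ratio scaling (adjusted p = 0.0854, 0.0558, 0.0662, 0.166 and 0.0558; 0.0043 to 0.166 over its alternatives). After quantile normalization the camera calls of the TCA cycle, fatty acid oxidation, mitochondrially encoded and ribosomal protein genes were lost (adjusted p = 0.155, 0.0795, 0.633 and 0.767, the highest over their alternatives).

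In total 3190 genes were higher and 658 lower in PH-failure (limma, adjusted p under 0.05), of which 504 and 70 by a factor of at least 2. After quantile normalization 1133 were higher and 1418 lower, and after median-ratio scaling 1530 and 1681. Of the 3848 genes, 3848 had the same direction within library series 56 and 3837 within series 55, where PH-failure has 1 library. The genes were called on these same libraries, so such agreement was nearly bound to follow and is no separate support. The count was 1540 without PH-failure replicate 3 and 2367 without replicate 2, and 1792 with the adipocyte score as a term.

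The comparison of PH-healthy with low PAP asks what differed in animals with a raised pressure and no clinical signs of failure. NPPB averaged 855 ± 14.6 against 19.9 ± 25.8 RPKM, log2 fold change 6.12 ± 0.79 (adjusted p = 0.000536), and ACTA1 averaged 4373 ± 620.0 against 368 ± 397 RPKM, log2 fold change 4.36 ± 0.90 (adjusted p = 0.00532). SCN3B rose to 228 ± 34.5 against 24.7 ± 22.8 RPKM, ANKRD2 to 207 ± 12.2 against 21.5 ± 8.52 RPKM, XIRP2 to 120.0 ± 9.81 against 13.7 ± 4.36 RPKM and FSTL3 to 31.8 ± 2.54 against 2.94 ± 2.01 RPKM. THBS4, a matrix glycoprotein, rose to 163 ± 109 against 16.0 ± 5.80 RPKM (adjusted p = 0.000515). MYL7 fell to 652 ± 158 against 4812 ± 1525 RPKM (-2.85 ± 0.36, adjusted p = 0.000407) and MAOB to 0.951 ± 0.521 against 21 ± 9.49 RPKM (-3.41 ± 0.43, adjusted p = 0.000384). LRRC3B, BEX2 and CA13 fell by 1.71, 1.78 and 2.08 on the log2 scale. MYH7 averaged 3653 ± 419.5 against 2610.5 ± 436 RPKM (adjusted p = 0.046), a call lost after quantile normalization, median-ratio scaling or non-mitochondrial scaling, with limma-voom, with no filter on low values and with the library series or the adipocyte score as a term. It was also lost without any 1 of low-PAP replicates 1 to 5 or of the PH-healthy libraries (adjusted p = 0.0505 to 0.166; 0.0228 to 0.28 over its alternatives). NPPA averaged 65.2 ± 17.7 against 33.6 ± 33.9 RPKM (adjusted p = 0.22).

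Of the 58 extracellular matrix and fibrosis genes, 39 rose in PH-healthy and none fell (45 adjusted over the list alone, 31 higher after quantile normalization; camera adjusted p = 1.06e-07, adjusted p = 0.926 with an estimated correlation). LTBP2 averaged 23.1 ± 5.38 against 2.86 ± 1.44 RPKM and TGFB2 5.54 ± 1.83 against 1.03 ± 0.371 RPKM. Of the growth and insulin/IGF signalling genes, 10 of 24 rose (14 adjusted over the list alone, 8 higher and 1 lower after quantile normalization; camera adjusted p = 0.0107, adjusted p = 0.926 with an estimated correlation). PDGFD (1.49 ± 0.17) and the receptor IGF2R (1.67 ± 0.28) were among them. Of the cytosolic ribosomal protein genes, 59 of 74 fell (64 adjusted over the list alone, 13 lower after quantile normalization; camera adjusted p = 1.29e-28, adjusted p = 0.926 with an estimated correlation). RPS26 averaged 224 ± 10.8 against 485 ± 111 RPKM and RPS29 487 ± 32.5 against 852 ± 142 RPKM. Of the oxidative phosphorylation genes, 47 of 79 fell (56 adjusted over the list alone, 2 higher and 14 lower after quantile normalization; camera adjusted p = 2.06e-24, adjusted p = 0.926 with an estimated correlation). COX7A1 averaged 1261 ± 71.9 against 2404 ± 465 RPKM. Of the fatty acid oxidation genes, 11 fell and 4 rose (11 and 4 adjusted over the list alone, 11 and 3 after quantile normalization; camera adjusted p = 0.000298, adjusted p = 0.926 with an estimated correlation). HADHB averaged 148 ± 31.15 against 333 ± 41.6 RPKM. Of the TCA cycle genes, 6 fell and 1 rose (6 and 2 adjusted over the list alone, 2 and 3 after quantile normalization; camera adjusted p = 0.0265, adjusted p = 0.946 with an estimated correlation). Of the 13 mitochondrially encoded genes 4 fell (4 adjusted over the list alone, 1 higher after quantile normalization; camera adjusted p = 0.0107, adjusted p = 0.926 with an estimated correlation). The medians of these lists, -0.10 and -0.15, became 0.12 and 0.02 after quantile normalization. There the camera calls of the fatty acid oxidation, TCA cycle and mitochondrially encoded genes were lost (adjusted p = 0.0825, 0.719 and 0.965, the highest over their alternatives). For the mitochondrially encoded genes this decides little, as quantile normalization hardly lets the most abundant genes differ. Without PH-healthy replicate 2 the calls of the TCA cycle and mitochondrially encoded genes were lost as well (adjusted p = 0.12 and 0.0601).

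The adipocyte marker score was 4.73 ± 0.448 in PH-healthy and 5.91 ± 1.1 in low PAP (exact permutation p = 0.119, adjusted p = 0.198 over the 20 tests). Of the 12 adipocyte markers measured, DGAT2, an enzyme of triglyceride synthesis, fell (71.1 ± 34.9 against 155 ± 18.1 RPKM) and ACACA, of fatty acid synthesis, rose by 0.37 (1 and 1 adjusted over the list alone, 3 and 0 after quantile normalization). The list was lower relative to the other genes, with a median of -0.57 against 0.18 for all tested genes (camera adjusted p = 0.0288, adjusted p = 0.926 with an estimated correlation). ACACA lost its call after quantile normalization or median-ratio scaling and without low-PAP replicate 3 or any 1 of the PH-healthy libraries (adjusted p = 0.0507 to 0.0922; 0.00931 to 0.422 over its alternatives). Of the T and NK cell markers, 1 of 14 fell (0 adjusted over the list alone, 3 lower after quantile normalization; camera adjusted p = 0.0053, adjusted p = 0.926 with an estimated correlation). Of the 18 glucocorticoid responsive genes, 1 fell (0 adjusted over the list alone, 2 lower after quantile normalization; camera adjusted p = 0.0221, adjusted p = 0.946 with an estimated correlation). This was GADD45B, at 12 ± 3.60 against 21.8 ± 4.82 RPKM, and its call was lost with no filter on low values, with the adipocyte score as a term and without low-PAP replicate 1, 2 or 5 or PH-healthy replicate 2 or 3 (adjusted p = 0.0508 to 0.122; 0.00868 to 0.157 over its alternatives). The camera call was lost for the T and NK cell markers without PH-healthy replicate 1 (adjusted p = 0.0679; 0.000224 to 0.0679 over its alternatives). That of the adipocyte markers was lost after quantile normalization, median-ratio scaling or non-mitochondrial scaling and with limma-voom (adjusted p = 0.158, 0.19, 0.0634 and 0.245), and without low-PAP replicate 5 or PH-healthy replicate 2 (adjusted p = 0.0642 and 0.107; 0.00883 to 0.245 over its alternatives). That of the glucocorticoid responsive genes was lost after quantile normalization or median-ratio scaling and with limma-voom (adjusted p = 0.191, 0.0799 and 0.0704), and without low-PAP replicate 6 or PH-healthy replicate 2 (adjusted p = 0.13 and 0.241; 0.000974 to 0.241 over its alternatives). In total 3024 genes were higher and 927 lower in PH-healthy (528 and 85 by a factor of at least 2). After quantile normalization 1424 were higher and 1622 lower, and after median-ratio scaling 1824 and 1861. All 3951 had the same direction within library series 56 and within series 55, which was nearly bound to follow, as they were called on these same libraries. The count was 1890, 2383 or 2248 without PH-healthy replicate 1, 2 or 3, and the list count of 10 was 6 without replicate 2.

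**Figure D3:**
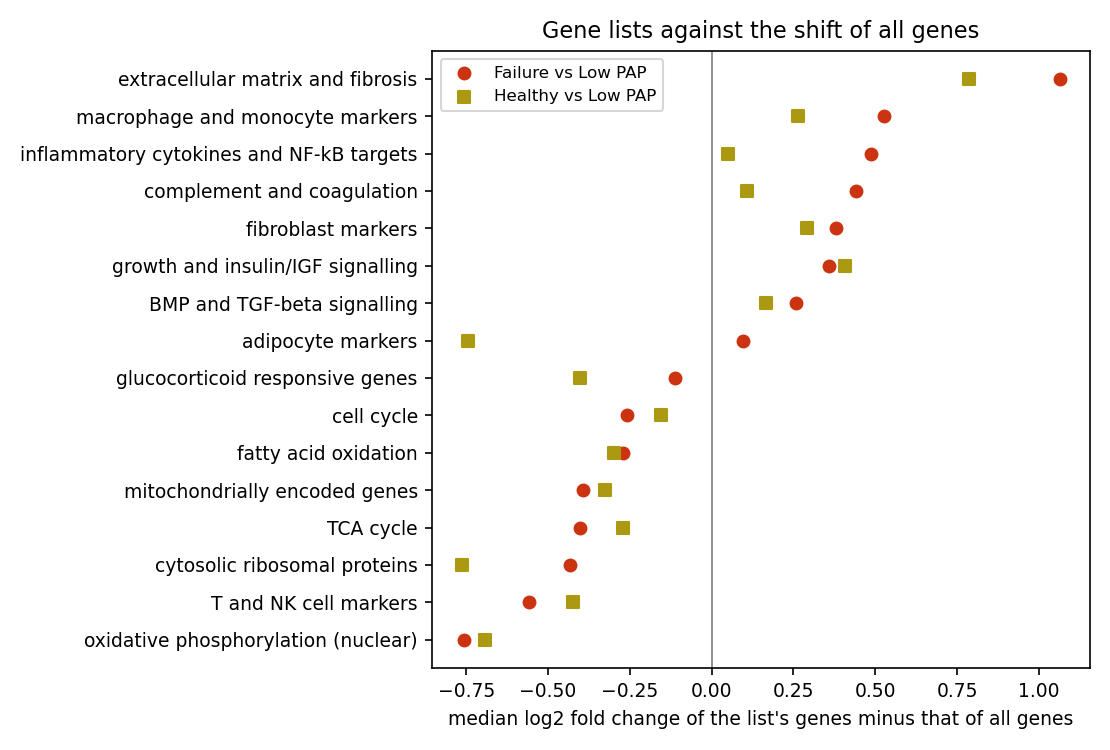
Median log2 fold change of the genes of each list minus the median of all genes, for PH-failure (circles) and PH-healthy (squares) against low PAP, for lists called by camera in either comparison. Extracellular matrix and fibrosis lies highest, at 1.06 and 0.79, and oxidative phosphorylation lies at -0.76 and -0.69; no list kept its call with an estimated correlation.

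The comparison of PH-failure with PH-healthy asks what differed between animals with a raised pressure that did and did not show heart failure. A locus named BPHL (ENSBTAG00000045888, chromosome 23, 50406551 to 50408215) averaged 7.25 ± 0.803 against 17.8 ± 0.143 RPKM, a log2 fold change of -1.19 ± 0.14 (limma adjusted p = 0.0154), and was the only gene of 11374 past the threshold. Its call was lost with the library series as a term (adjusted p = 0.0548), with limma-voom (0.236) and with the adipocyte score as a term (0.397). It was also lost with only the groups compared (adjusted p = 0.104) and without PH-healthy replicate 1, 2 or 3 (0.142, 0.0658 and 0.143) or PH-failure replicate 1 or 3 (0.0544 and 0.102; 0.00282 to 0.397 over its alternatives). The locus was lower within library series 56 (7.81 and 7.62 RPKM in PH-failure against 17.8 in PH-healthy) and within series 55 (6.33 against 17.7 and 18.0). It lies within the longer BPHL gene (ENSBTAG00000006379, chromosome 23, 50394684 to 50417050), which averaged 7.63 ± 1.5 against 14.2 ± 0.564 RPKM (-0.83 ± 0.20) and did not pass. How reads that fall in both loci were counted is not given in the sources used here, so both values are uncertain. A locus named TUBB2B (ENSBTAG00000004093, chromosome 23, 50354843 to 50357631), a beta-tubulin whose symbol another locus carries too, averaged 7.98 ± 1.21 against 1.09 ± 0.477 RPKM, log2 fold change 2.12 ± 0.35 (adjusted p = 0.209, and 0.000972 without low-PAP replicate 5; 0.000972 to 1 over its alternatives). THOC7, of the mRNA export complex THO, averaged 1.80 ± 0.485 against 13.8 ± 5.22 RPKM, log2 fold change -2.36 ± 0.53, and did not pass (adjusted p = 1, and 0.00443 without low-PAP replicate 2; 0.00443 to 1 over its alternatives). RGS16, a regulator of G protein signalling, averaged 2.63 ± 0.322 against 1.05 ± 0.475 RPKM, RRAD, a small GTPase of muscle, 139 ± 28.9 against 74.1 ± 4.11 RPKM, and TUBA1B, an alpha-tubulin, 231 ± 9.02 against 152 ± 16.5 RPKM, none of them past the threshold. NPPB differed by -0.30 ± 0.91, NPPA by -0.45 ± 0.94, ACTA1 by -1.05 ± 1.04 and MYH7 by -0.20 ± 0.21 on the log2 scale, none past the threshold. Without PH-failure replicate 2 the differences of NPPB and NPPA were 0.053 and 0.43. Without any 1 library they ranged over -0.95 to 0.053 and -1.64 to 0.43, and that of ACTA1 over -1.80 to -0.41.

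No member of any list passed over all genes. Adjusted over the list alone, 6 of 27 complement and coagulation genes were higher in PH-failure (camera adjusted p = 6.29e-08, adjusted p = 0.529 with an estimated correlation). C1R averaged 23.2 ± 8.64 against 10.7 ± 0.356 RPKM and C7 86.9 ± 44.2 against 31.6 ± 16.9 RPKM. C1R and C1S passed over all genes without PH-failure replicate 2 (adjusted p = 0.0306 and 0.0434; 0.0306 to 1 and 0.0434 to 1 over their alternatives). Adjusted over the list alone, 4 of 12 adipocyte markers were higher (camera adjusted p = 0.000881, adjusted p = 0.529 with an estimated correlation). ADIPOQ, the adipocyte hormone adiponectin, was at 49.6, 3.62 and 70.5 RPKM in PH-failure replicates 1, 2 and 3 and averaged 0.927 ± 0.314 in PH-healthy. The adipocyte marker score was 7.67 ± 2.30 against 4.73 ± 0.448 (exact permutation p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.195). The 74 cytosolic ribosomal protein genes had a median difference of 0.36 with 0 members past the threshold, also 0 adjusted over the list alone (camera adjusted p = 2.86e-29, adjusted p = 0.529 with an estimated correlation). In all, camera with the preset correlation gave 23 lists, 17 higher and 6 lower in PH-failure relative to the other genes. None kept its call with an estimated correlation (adjusted p = 0.529 to 0.761 with an estimated correlation).

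Inflammatory cytokine and NF-kB genes (median difference 0.28), fibroblast markers (0.30), macrophage and monocyte markers (0.33) and extracellular matrix genes (0.24) were among the higher lists. Among their members, CCL2, which attracts monocytes, averaged 10.3 ± 3.36 against 4.54 ± 3.82 RPKM, the fibroblast receptor PDGFRA 10.8 ± 5.65 against 5.94 ± 0.684 RPKM and POSTN (periostin) 318 ± 132 against 189 ± 27.0 RPKM, none past the threshold. CCL2 passed without PH-healthy replicate 2 (adjusted p = 0.0412; 0.0412 to 1 over its alternatives). The camera call of the extracellular matrix genes was lost without PH-failure replicate 3 or PH-healthy replicate 3 (adjusted p = 0.208 and 0.199). Without the latter its direction turned. That of the macrophage list was lost with the adipocyte score (0.0666). It was also lost without PH-healthy replicate 3 or PH-failure replicate 1 or 3 (0.124, 0.0585 and 0.248). That of the fibroblast list was lost without PH-healthy replicate 3 or PH-failure replicate 1 (0.336 and 0.133). MHC class II genes (-0.36), calcium handling and ion channel genes (-0.08) and TCA cycle genes (-0.11) were among the lower lists. The MHC class II call was lost without PH-healthy replicate 2 (camera adjusted p = 0.181). Its direction turned without PH-failure replicate 3 (0.419) and with the adipocyte score (0.0666). In PH-failure replicates 1, 2 and 3 BOLA-DQA2 was at 52.0, 0.141 and 0.144 RPKM and BOLA-DQA5 at 14.2, 0.183 and 0.187. BOLA-DQA1 (0.11 to 1.31) and BOLA-DQB (0.18 to 0.63) had positive differences without any 1 library. The nuclear oxidative phosphorylation genes were lower as well (-0.06), but higher by camera without PH-failure replicate 3 (adjusted p = 0.00012; 1.58e-15 to 0.563 over its alternatives). With the adipocyte score, which did not overlap between the PH groups, as a term 7 lists were called, and 18 of the 23 calls were lost. Among these were the inflammatory list (adjusted p = 0.563; 2.18e-08 to 0.563 over its alternatives) and the ribosomal protein list, whose direction turned (adjusted p = 0.602; 2.27e-35 to 0.602 over its alternatives). At the preset correlation, the complement list kept its camera call in all 19 settings tried for lists. Of the 23 calls, 15 were lost or turned without PH-failure replicate 3, 9 without PH-healthy replicate 3, 7 without PH-failure replicate 1, 5 without PH-healthy replicate 2, 2 without PH-failure replicate 2, 2 without PH-healthy replicate 1 and 1 without low-PAP replicate 3 or 4. The library series as a term, quantile normalization and median-ratio scaling each lost or turned 1. Without PH-failure replicate 3 the number of lists was 11. The number of genes was 0 without PH-healthy replicate 1 or 3 or PH-failure replicate 1 or 3, 2 without low-PAP replicate 2 (BPHL and THOC7) or 5 (BPHL and TUBB2B), and 4 without PH-failure replicate 2 (BPHL, C1R, C1S and CHI3L1, the last chosen here after its values were seen), and without PH-healthy replicate 2 CCL2 was the 1 gene that passed. With limma 308 genes had an unadjusted p under 0.05, and limma-voom called 0 genes, with 281 at an unadjusted p under 0.05. Both counts lie below a share of 0.05 of the tested genes, which unchanged genes would give on average. They show no excess of small p-values.

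All 6 animals with pulmonary hypertension were also compared with the 6 low-PAP animals. NPPB averaged 860.3 ± 463 against 19.9 ± 25.8 RPKM, log2 fold change 5.97 ± 0.64 (n = 6 and n = 6, adjusted p = 9.47e-05 by limma), ANKRD2 246 ± 99.4 against 21.5 ± 8.52 RPKM, log2 fold change 3.44 ± 0.28 (adjusted p = 1.48e-05) and PI16 57.1 ± 17.8 against 6.64 ± 3.00 RPKM, log2 fold change 2.93 ± 0.26 (adjusted p = 2.26e-05). MYL7 averaged 776 ± 413 against 4812 ± 1525 RPKM, log2 fold change -2.71 ± 0.30 (adjusted p = 8.01e-05), HRASLS 9.12 ± 3.19 against 34.2 ± 7.74 RPKM (adjusted p = 2.59e-05) and FAH, the last enzyme of tyrosine breakdown, 4.04 ± 0.995 against 13.5 ± 3.88 RPKM (adjusted p = 0.000118). In this comparison 49 of 58 extracellular matrix genes rose (51 adjusted over the list alone, 45 higher after quantile normalization; camera adjusted p = 2.19e-09, adjusted p = 0.786 with an estimated correlation). Of the growth and insulin/IGF genes, 16 of 24 rose (18 adjusted over the list alone, 11 higher and 1 lower after quantile normalization; camera adjusted p = 0.00445, adjusted p = 0.786 with an estimated correlation). Of the oxidative phosphorylation genes 61 of 79 fell (66 adjusted over the list alone, 1 higher and 38 lower after quantile normalization; camera adjusted p = 3.93e-30, adjusted p = 0.786 with an estimated correlation). Of the ribosomal protein genes 40 of 74 fell (45 adjusted over the list alone, 8 lower after quantile normalization; camera adjusted p = 9.04e-22, adjusted p = 0.786 with an estimated correlation). As given above, most of them fell in PH-healthy but few in PH-failure. Of the T and NK cell markers 4 of 14 fell (3 adjusted over the list alone, 11 lower after quantile normalization; camera adjusted p = 0.0002, adjusted p = 0.786 with an estimated correlation). The other called lists were fatty acid oxidation (12 fell, 5 rose; camera adjusted p = 0.0002, adjusted p = 0.786 with an estimated correlation) and the TCA cycle (7 fell, 2 rose; camera adjusted p = 0.00108, adjusted p = 0.884 with an estimated correlation). So were the mitochondrially encoded genes (5 fell, 1 rose; camera adjusted p = 0.00173, adjusted p = 0.786 with an estimated correlation). Adjusted over the list alone the counts were 12 and 5, 7 and 2, and 5 and 1. The median of the mitochondrially encoded genes was -0.17, and 0.06 after quantile normalization. There the camera calls of these 3 lists were lost (adjusted p = 0.0634, 0.78 and 0.814, the highest over their alternatives), which for the abundant mitochondrially encoded genes decides little. In total 4243 genes were higher and 1178 lower in PH, 1930 and 2405 after quantile normalization, and 2504 and 2542 after median-ratio scaling. All 5421 had the same direction within library series 56 and within series 55, again nearly bound to follow from calling them on these same libraries.

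The authors' deposited table compares high with low PAP and lists 1016 genes with a false discovery rate under 0.05, 385 higher and 631 lower at high PAP. Of these, 966 also passed in the comparison of all PH with low PAP here, 0 of them with the opposite sign. Across 11374 genes, which are not independent replicates, Spearman's correlation of the log2 folds in the authors' deposited table with those here was 0.978. The authors' values appear to share most libraries with those here, so such agreement was nearly bound to follow and is no separate support. The balance of calls differed, as here 4243 genes were higher and 1178 lower in PH. For NPPB the authors' deposited table gives a signed fold (negative where lower at high PAP) of 42.5, for ANKRD2 10.1 and for MYL7 -6.68.

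Both PH groups were compared with the same low-PAP libraries, and 2439 genes were higher and 513 lower in both comparisons, with 1 called in opposite directions. That gene, chosen here after its values were seen, was the TUBB2B locus ENSBTAG00000004093, with log2 fold changes of 1.14 in PH-failure and -0.97 in PH-healthy (limma adjusted p = 0.015 and 0.0259; 0.00614 to 0.0653 and 0.00121 to 0.108 over the alternatives). The call in PH-failure was lost after quantile normalization (adjusted p = 0.054) and without PH-failure replicate 3 (0.0653), and that in PH-healthy without low-PAP replicate 4 (0.0517) or PH-healthy replicate 1 or 3 (0.0784 and 0.108). Independent lists of these sizes would share 848 and 53.6 genes. The 6 shared genes with the smallest p were NES (nestin, an intermediate filament protein), the taurine transporter SLC6A6, DDAH2, DACT1, RAB33A and DUSP27. NES averaged 247 ± 44.8 RPKM in PH-failure and 292 ± 18.0 in PH-healthy against 41.1 ± 5.62 in low PAP, and SLC6A6 averaged 8.20 ± 2.07 and 9.57 ± 3.70 against 0.672 ± 0.116. DDAH2, which breaks down an inhibitor of nitric oxide synthesis, averaged 77.4 ± 27.6 and 84.9 ± 22.2 against 14.68 ± 1.68. Across genes, which are not independent replicates, the log2 fold changes of the PH groups had a correlation of 0.889 and a covariance of 0.209. In 100 simulations of unchanged groups against shared controls these averaged 0.333 and 0.0143. Genes were drawn independently there, so this correlation follows from the group sizes. The simulations do not show how far it can vary when genes move together. With the low-PAP libraries split 3 and 3, so that no control was shared, the median correlation over 20 splits was 0.814 (0.717 to 0.855) and the median covariance 0.199. These splits, with 3 controls each, shared medians of 268 higher and 27 lower genes. The overlap of 2952 genes was 1954 after quantile normalization and 1492 with the adipocyte score as a term. It was 1429 and 1738 without PH-failure replicates 3 and 2, 1624, 1889 and 1912 without PH-healthy replicates 1, 2 and 3, and 1900 without low-PAP replicate 3.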

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

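The tests of PH-failure replicate 3, of reads moved between the TUBB2B loci and of an inherited difference were chosen only after the result was seen. With the preset correlation 23 lists differed between PH-failure and PH-healthy, 17 of them higher in PH-failure relative to the other genes, although 1 gene passed. Different amounts of fat in the tissue pieces stay a possible part of the cause. With the adipocyte score as a term 5 of the 17 lists stayed called higher, but this cannot decide it. The score was 5.44 to 10.03 in PH-failure and 4.28 to 5.17 in PH-healthy, so as a term it takes up group differences of any cause. Its genes also belong to the adipocyte list, which is among the 17. ADIPOQ, FABP4 and CIDEC reached 70.5, 949 and 8.44 RPKM in PH-failure replicate 3, against at most 1.29, 4.01 and 0.183 in PH-healthy, and FABP4 is on the endothelial list too. PH-failure replicate 3 alone may also carry part of the list difference, since without that library 7 of the 17 lists stayed called higher. The real split gave 23 lists and the highest of the other splits 22, and 1 of 10 splits gave as many as the real one; 10 splits are too few for a share under 0.05, and heart failure itself stays open as untested.

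The BPHL locus within the longer BPHL gene was lower in PH-failure than in PH-healthy by a log2 fold change of -1.19, while the TUBB2B locus, a neighbour of BPHL in the RefSeq annotation of assembly ARS-UCD2.0, was higher without passing. A lower depth of PH-failure replicate 1 is argued against, since without that library the difference was -1.24. Reads moved between the TUBB2B loci cannot be told apart from a real difference, because the sum of both TUBB2B loci was higher by 6.17 ± 7.17 RPM (SE), or 0.860 standard errors, with 9.88 from this locus and -3.71 from the other. An inherited difference that moves both genes may be a candidate explanation. It was tested with the longer BPHL gene, not the called locus within it, against this TUBB2B locus. In the 6 low-PAP libraries their Pearson's r was -0.881 (exact permutation p = 0.101) and Spearman's rho -0.486 (exact permutation p = 0.356). Without the 2 libraries farthest from the median r was 0.894, so the relation rests on those libraries. For the number of genes, the real split gave 1 and the highest of the other splits 3, 4 of 10 splits gave at least 1, and 10 splits are too few for a share under 0.05.

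In the low-PAP group, 13 of 194 measures had a library far from the other 5, where chance gives about 1 in 20. TUBB2B (ENSBTAG00000004093) was at 0.763 RPKM in replicate 5 and 3.01 to 4.35 in the others. BPHL was at 25.7 RPKM in the same library, against 13.5 to 17.1. Replicate 5 also had CLU at 60.4 RPKM (27.7 to 35.4 in the others), PC at 1.48 (0.443 to 0.665) and an adipocyte marker score of 7.98 (4.91 to 6.00). THOC7 was at 1.83 RPKM in replicate 2 and 10.9 to 16.0 in the others, and KCNIP2 at 4.36 (6.89 to 8.87). Replicate 1 had a mitochondrial share of 29.9% (22.5 to 24.6% in the others), COX1 at 80945 RPKM (52421 to 58636), IDH2 at 405 (500.4 to 543) and BOLA-DQA2 at 2.20 (24.2 to 37.9). DUSP27 was at 5.05 RPKM in replicate 3 (6.63 to 7.48 in the others) and LTBP2 at 5.75 in replicate 6 (1.79 to 2.63).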

How the results depend on the processing

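Median-ratio scaling, non-mitochondrial scaling, limma-voom, the residual component and the adipocyte score were chosen only after the data were seen. The genes called in PH-failure against low PAP (3848) numbered 2551 after quantile normalization, 2393 with at least 5 RPKM (fewer genes tested) and 1792 with the adipocyte score. Those in PH-healthy (3951) and in all PH (5421) numbered 2557 and 3416 with at least 5 RPKM, and the overlap (2952) 1954 after quantile normalization, 1891 with at least 5 RPKM, 1492 with the adipocyte score and a median of 294.5 over 20 splits of the low-PAP libraries (fewer samples). PH-failure against PH-healthy gave 0 genes by limma with the library series as a term (414 at an unadjusted p under 0.05), limma-voom (281), the adipocyte score (112), only the groups compared (230) or the replicate block (250). Each of these unadjusted counts lies below the share of 0.05 that unchanged genes would give on average. Leaving out 1 library gave 1540 to 4669 genes in PH-failure, 1890 to 4643 in PH-healthy, 0 to 4 between them, 4422 to 5977 in all PH and 1429 to 3745 in the overlap, and 11 to 17, 6 to 12, 11 to 25 and 8 to 12 lists. With an estimated correlation camera called 0 lists in each comparison, with 1, 0, 2 and 1 at an unadjusted p under 0.05. fry called 24, 6, 0 (1 at an unadjusted p under 0.05) and 23, against 14, 10, 23 and 8. Quantile normalization gave 16 in all PH, and the adipocyte score 7 between the PH groups. Other settings stayed within a factor of 1.5 of these counts. The cause was not tested, except where fewer genes or samples are named.

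Replicate numbers do not pair the animals: same-numbered libraries of different groups deviated from their group means with correlations of -0.257 to 0.193, and not every library correlated best with its own number. Replicate numbers 4 to 6 occur only in low PAP, so the block fits those libraries exactly and they no longer count as controls (fewer samples). The replicate block gave 1379, 1834, 0 and 3027 genes and an overlap of 1153. With it the camera calls were lost for the macrophage and monocyte markers in PH-failure (adjusted p = 0.216; 0.000225 to 0.216 over its alternatives) and for the TCA cycle genes (0.149; 0.0057 to 0.719 over its alternatives), the adipocyte markers (0.0694; 0.00883 to 0.245 over its alternatives) and the glucocorticoid responsive genes (0.0825; 0.000974 to 0.241 over its alternatives) in PH-healthy. Of the gene calls given in the text, the block ended those of ACTA1, SUCLA2 and TRAC in PH-failure, of MYH7, DGAT2, ACACA and GADD45B in PH-healthy and of the BPHL locus between the PH groups.

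For named genes, 6910 of the refitted values kept direction and side of the threshold, 252 lost and 64 gained the call, and 15 changed sign, all in genes that were not called. NPPA in PH-failure against low PAP was at -0.32 without PH-failure replicate 1 (-0.32 to 1.75 without any 1 library). Between PH-failure and PH-healthy, NPPA was at 0.43 and NPPB at 0.053 without PH-failure replicate 2, and KCNIP2 at 0.030, IDH2 at 0.030 and S100A12 at -0.024 without replicate 3; without any 1 library they ranged over -1.64 to 0.43, -0.95 to 0.053, -0.64 to 0.030, -0.35 to 0.030 and -0.024 to 1.57, in that order. With the adipocyte score, ACTA1 was at 1.06, KCNIP2 at 0.060, PC at -0.13, EDN1 at -0.10, SMAD6 at -0.0098, EGFL7 at -0.018, C1QC at -0.050, S100A12 at -0.12 and LCK at 0.020 (log2). The planned count models (DESeq2, edgeR with other size factors, voom with TMM) and sva were not run. The plan set limma-trend for a file without counts, although the recovered reads would have allowed count models. Depth limits low genes most.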

Other observations

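The tests of the scaling and of mitochondrial reads were chosen only after the result was seen. Of the 19 measured genes of the heart's stress and fetal program, 10 rose and 3 fell (11 and 3 adjusted over the list alone, 9 and 1 after quantile normalization) in PH-failure against low PAP and 12 rose and 2 fell (12 and 3 adjusted over the list alone, 9 and 2 after quantile normalization) in PH-healthy, so members moved both ways and camera called the list in neither comparison (adjusted p = 0.236 and 0.107). NPPB, ACTA1, ANKRD2, XIRP2 and NES rose in both, while MYL7 fell in both. Over all 11374 tested genes, 3190 rose and 658 fell in PH-failure, 3024 and 927 in PH-healthy, and 4243 and 1178 in all PH. In all PH against low PAP, of the 18 smooth muscle and pericyte markers 12 rose and 3 fell (12 and 3 adjusted over the list alone, 8 and 2 after quantile normalization) (camera adjusted p = 0.41), of the 23 endothelial markers 12 rose and 1 fell (12 and 1 adjusted over the list alone, 8 and 1 after quantile normalization) (camera adjusted p = 0.277) and of the 5 lymphatic markers 4 rose and 0 fell (4 and 0 adjusted over the list alone, 3 and 0 after quantile normalization) (camera adjusted p = 0.171). Of the 28 hypoxia and HIF target genes 12 rose and 2 fell (12 and 2 adjusted over the list alone, 6 and 2 after quantile normalization) (camera adjusted p = 0.41), shares near those over all tested genes. Of the 23 heat shock and chaperone genes 12 rose and 0 fell (12 and 1 adjusted over the list alone, 9 and 0 after quantile normalization) (camera adjusted p = 0.141), of the 21 unfolded protein response genes 12 rose and 0 fell (12 and 0 adjusted over the list alone, 8 and 0 after quantile normalization) (camera adjusted p = 0.187) and of the 29 interferon response genes 14 rose and 0 fell (14 and 0 adjusted over the list alone, 0 and 0 after quantile normalization) (camera adjusted p = 0.203).

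Of the 22 beta-adrenergic signalling genes 12 rose and 3 fell (13 and 3 adjusted over the list alone, 8 and 2 after quantile normalization) in all PH (camera adjusted p = 0.457), with PPP1R1A among those that fell. This count and those below stand beside 4243 higher and 1178 lower genes of the 11374 tested. Of the 26 calcium handling and ion channel genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, 10 and 1 after quantile normalization) (camera adjusted p = 0.433) and of the 23 sarcomere genes 8 rose and 6 fell (8 and 6 adjusted over the list alone, 10 and 3 after quantile normalization) (camera adjusted p = 0.396). Of the 16 circadian clock genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, 5 and 1 after quantile normalization) (camera adjusted p = 0.3) and of the 19 renin-angiotensin and endothelin genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 3 and 1 after quantile normalization) (camera adjusted p = 0.385). Skeletal muscle markers (camera adjusted p = 0.811), atrial and conduction markers (camera adjusted p = 0.95), mast cell markers (camera adjusted p = 0.987), erythroid markers (camera adjusted p = 0.95) and neuronal and Schwann cell markers (camera adjusted p = 0.879) were not called. Of the 15 mesothelial markers 2 were measured, too few for a test. THOC7, chosen here after its values were seen, lay at 1.28, 1.88 and 2.24 RPKM in the PH-failure libraries and at 1.83 in low-PAP replicate 2, while the other 8 libraries lay between 9.81 and 19.7.

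More genes were called higher than lower in PH, 82.9% of calls in PH-failure, 76.5% in PH-healthy and 78.3% in all PH. The calls in the authors' deposited table, by a test that is not given, go the other way, with 385 genes higher and 631 lower at high PAP. A smaller share of mitochondrial reads alone is argued against as the whole cause of the excess here, since after scaling to reads outside the mitochondrial genes 68.8% of calls in PH-failure were still higher. The scaling of RPKM to all mapped reads cannot be told apart from a real excess. With median-ratio scaling the largest share of higher calls over the 3 comparisons was 49.6%, but that scaling sets the median log2 fold change of all genes near 0 by construction (0.0066, -0.00056 and 0.0035), so it decides nothing. The 20 most abundant genes took 31.6 ± 2.17% of exon reads in PH and 36.6 ± 2.03% in low PAP (exact permutation p = 0.00216, adjusted 0.0216). Whether total RNA per cell differed stays open, as no measure of it was used here.

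In the comparisons with low PAP, the other splits tried gave fewer genes than the groups did. For PH-failure against low PAP, 1 of 84 splits, the real one, gave as many as 3848 genes, and the highest other gave 1911, with PH-failure replicates 2 and 3 and low-PAP replicate 6 on 1 side. For PH-healthy, 1 of 84 gave as many as 3951 and the highest other gave 1221. For all PH, in a fit of 2 groups, 1 of 100 drawn splits gave as many as 5558 genes, and the highest other gave 4632, a split in which low-PAP replicate 6 and PH-failure replicate 1 changed places. A chance split is thus unlikely to give these gene counts, but it is not excluded, as the real split alone is the smallest share that the splits allow. For the overlap of 2952 genes the splits decide nothing. Of 100 drawn regroupings, 1, the real one, gave as many and the highest other gave 0, but only 1 of the 99 others called genes in both comparisons, so the others were nearly bound to give 0. Chance cannot be excluded for the list counts against low PAP. As many as 14 lists came from 35 of 84 splits in PH-failure (highest other 23), as many as 10 from 53 of 84 in PH-healthy (highest other 21) and as many as 8 from 87 of 100 in all PH (highest other 23).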
